A study of Mus musculus with 3 samples.

How the data were processed

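H3K9ac CUT&Tag libraries of sorted mouse bone marrow HSCs were analysed, 1 for each of 3 groups: young HSC, old HSC and old HSC ABC. Ages (2 to 4 and 18 to 24 months) were read from the labels' protocol and the y or o that opens each title. Per the submitters' processing notes, BWA, Picard, MACS2 and edgeR were used and the build was mm10; the role and version of each tool, the control library and the peak calling settings are not given in the sources used here. Each deposited file listed summits of 1 bp with a name and a score. The authors' score is read here as the −log10 q-value of MACS2 in that library, because each list starts just above 1.30, the −log10 of 0.05. Each list belonged to 1 sample, so peaks were taken as called per library. A score depends on the depth of its library, which was unknown, so scores were used to rank and filter summits within a list and were not compared between lists. Read depth is not given in the sources used here, so no floor or interval that needs it is given.

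Groups were taken from the labels. The sample names inside the peak names disagreed with them: oHSC-H3K9ac-1 in the list labelled young, oHSC-ABC-H3K9ac-1 in the list labelled old and oHSC-H3K9ac-2 in the list labelled old ABC. Which of these is right could not be settled from the files, so libraries are named by their label throughout.

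Gene records came from the RefSeq gene table of GRCm38.p6, whose coordinates are those of mm10. It held 49997 records, of which the 21883 protein-coding ones on chromosomes 1 to 19, X and Y were used. The table gives start and end of a gene but no strand, start site or exons. The plan, written before the data were examined, was to count summits within 1 kb of a transcription start site; in its place a gene was taken to have an end summit if a summit lay within 1 kb of either end of its record. A gene could thus count as marked in 2 libraries with summits at opposite ends of its record. Exon, intron and UTR positions were not analysed here. Summits of 2 lists counted as shared if within 500 bp. Differences between libraries were counted as genes with an end summit in one library and none in the other. A difference of this kind can arise from a summit just outside the window, so the distance of the nearest summit is given beside many of the named genes.

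No test was possible with 1 library per group. Shares have exact 95% Clopper-Pearson binomial intervals on numbers of summits or genes. These cover counting error only and leave out the spread between libraries of a group. A list of summits grows with depth, so each comparison was repeated on equal-length lists of the 33248 highest-scoring summits, 33248 being the length of the shortest list. The old-labelled library serves in 2 contrasts, and the overlap of genes absent from both others was set beside 100 simulations within 10 bins of old-labelled score.

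A total of 20 gene lists were fixed before the data were examined: HSC identity, HSC ageing, ferroptosis, sphingolipid metabolism, histone acetylation enzymes, senescence and p53, interferon response, NF-kB, oxidative phosphorylation, glycolysis and hypoxia, autophagy and lysosome, cell cycle, ribosomal proteins, markers of megakaryocytes and platelets, of erythroid, myeloid, B, T and NK cells and of stroma and endothelium, and control genes of other tissues. Of 510 list entries, 503 were matched to a gene by symbol or synonym, with a few genes in more than one list; Mx1 and Ahsp had no protein-coding record, and the other names repeated a gene of the same list under an older symbol. The members of a list were counted against 10000 random lists with the same number of genes in each of 10 bins of gene length. This replaced matching on promoter CpG content, as planned for the case that no sequence was at hand. A percentile counts random lists below the observed count plus those at it with a weight of 0.5. These percentiles are descriptions, not p-values.

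Named genes followed a rule fixed beforehand: 18 genes always; per comparison, direction and list up to 3 members that differed both as deposited and in equal-length lists, by score; and per comparison and direction the 8 genes with the highest-scoring end summit and no summit within 5 kb of an end in the other library, leaving out Gm, Rik and olfactory receptor genes. This gave 149 genes, of which the text names a part. Genes named outside this rule (further list members behind a count, examples of the control genes, S100a8, S100a9 and the other granulocyte genes) were chosen after their values were seen.

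The alternatives planned beforehand were scores of at least 5 and 10, equal-length lists, merging of summits closer than 500 bp, sharing within 250 or 1000 bp, gene ends within 500 bp or 2 kb, and chromosomes 1 to 19 and X only. Added after the data were seen were summits anywhere in a gene record, summits at 1 gene only, absence within 5 kb with lists as deposited or of equal length, random lists from genes marked in either library, and groups from the peak names. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1. The procedure was tested on simulated lists: all 116 planted differences between old and young among 12615 isolated genes were recovered, and 1000 random lists had a median percentile of 48.5. The number of random lists in that test was raised to 1000 after smaller draws had given medians further from 50. Planted summits were placed inside the 1 kb window, so their recovery was fixed in advance and checked the code only. Differences in depth, threshold or summit position across the window edge were not simulated.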

Results

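H3K9ac, an acetylation mark of histone H3 that is enriched at active promoters and enhancers, was profiled by CUT&Tag in sorted mouse haematopoietic stem cells (HSCs). In CUT&Tag an antibody brings a transposase to the mark, and the transposase cuts out and tags the DNA around it. Bone marrow came from wild-type mice aged 2 to 4 months or 18 to 24 months, and 50000 sorted HSCs were used per assay. There were 3 libraries, 1 in each group: young HSC, old HSC and old HSC with the label ABC, which the labels do not spell out. With 1 library per group there was no replicate check on any difference, so no test was run and no p-value is given. The values were summit positions in mm10 and a score for each summit from the authors' peak calling, used only to rank or filter summits within its own list. Read depth was unknown. The sample names written inside the peak names did not match the labels: the list labelled young carried the name of an old HSC sample, the list labelled old carried that of an old HSC ABC sample, and the list labelled old ABC carried that of another old HSC sample. Groups follow the labels, and each direction below holds for the libraries as labelled.

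The library labelled old had 108787 summits, 3.27 times the 33248 of the library labelled young, and the library labelled old ABC had 45386, or 1.37 times. Summits within 1 kb of either end of a protein-coding gene record (end summits) made up 28.4% of the young-labelled list (95% Clopper-Pearson interval 27.9 to 28.9), 13.0% of the old-labelled list (12.8 to 13.2) and 22.3% of the ABC-labelled list (21.9 to 22.7). These intervals cover counting error only. A further 48.3%, 56.5% and 52.0% of summits lay elsewhere inside gene records, and 23.4%, 30.5% and 25.7% lay outside them. When each list was limited to its 33248 highest-scoring summits, called equal-length lists here, the shares at gene ends were 28.4%, 28.9% and 27.2%. The 9 strongest positions of the young-labelled list were among the 10 strongest of both other lists, led by chromosome 2 position 98667142, with scores of 1383, 2254 and 1331 in the young-, old- and ABC-labelled lists. No filter for regions of artefact signal was applied here, so these shared positions are not read as sites of H3K9ac.

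**Figure D1:**
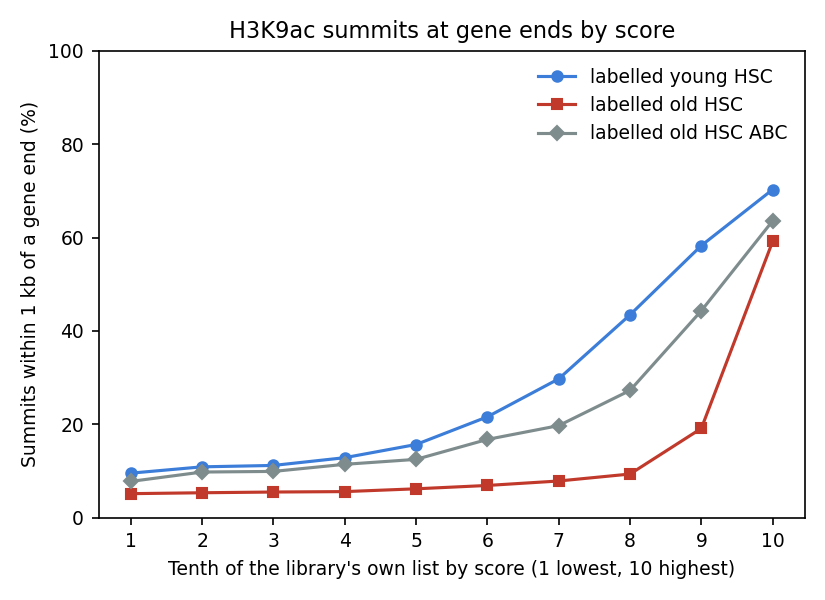
Share of summits within 1 kb of a gene end (y axis, percent) in each of 10 equal bins of a library's own list ordered by score (x axis, 1 lowest to 10 highest), with 1 line per library. In the highest bin the share was 70.3%, 59.2% and 63.6% in the libraries labelled young, old and old ABC, and in the lowest bin it was 9.56%, 5.18% and 7.80%.

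Most summits of the smaller lists had a counterpart in the largest one. Of the young-labelled summits 77.4% lay within 500 bp of an old-labelled summit (76.9 to 77.8) and 59.0% within 500 bp of an ABC-labelled one (58.5 to 59.6). Of the ABC-labelled summits 72.4% had an old-labelled and 43.5% a young-labelled neighbour, while 23.8% and 30.3% of the old-labelled summits had a young- or ABC-labelled one. In equal-length lists all 6 shares lay between 52.7% and 56.1%. Of the 21883 protein-coding genes, 9170 had an end summit in the young-labelled library, 12454 in the old-labelled and 9531 in the ABC-labelled library. In all 3 libraries 7948 genes had one, and 8770 genes had none in any library.

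Among the genes named in advance for their link to the study's subject, Sphk1, a kinase that makes sphingosine 1-phosphate (chromosome 11, 116530836 to 116536675), had no summit within 5 kb of either end in any library. Sphk2, the other sphingosine kinase (chromosome 7, 45709463 to 45718002), had an end summit in all 3, with scores of 19.3, 20.5 and 6.39 in the young-, old- and ABC-labelled lists. The summits with these scores lay beyond the Sphk2 record, inside the overlapping record of Rpl18 (45715467 to 45720835). They cannot be assigned to Sphk2 alone. Another ABC-labelled summit lay 6 bp from an end of Sphk2. Gpx4, which reduces lipid peroxides and blocks ferroptosis, had its nearest summits 2086, 1949 and 1589 bp from a record end, so it did not count as having an end summit. Its record held 2, 2 and 1 summits in the young-, old- and ABC-labelled lists. Slc7a11, the cystine transporter subunit, had no summit within 5 kb of an end in any library, but its record held 3, 4 and 1. Acsl4, which joins polyunsaturated fatty acids to coenzyme A, and Tfrc, the transferrin receptor, had end summits in all 3. Fth1, the ferritin heavy chain, also had one in all 3, but its ABC-labelled summit (score 2.82) did not reach the equal-length list. Hmox1, haem oxygenase 1 (chromosome 8, 75093618 to 75100593), had one in the young-labelled (6.71) and old-labelled (3.72) lists, and its nearest ABC-labelled summit was 8532 bp away. The deacetylase genes Hdac1 and Hdac2 had end summits in all 3 libraries, and the acetyltransferase gene Kat2a had one in the old-labelled (5.88) and ABC-labelled (4.28) lists and a nearest young-labelled summit at 1222 bp. The old- and ABC-labelled summits of Kat2a lay at opposite ends of its record, at 100711941 and 100704228, so they are not the same site. Procr, which encodes the HSC surface receptor EPCR, was marked at an end in all 3. Hlf and Selp, an HSC transcription factor and P-selectin, had weak end summits in the old-labelled list alone (3.04 and 2.00). Neither reached the old-labelled equal-length list. The nearest young- and ABC-labelled summits lay at 2183 and 2179 bp for Hlf and at 1774 and 1183 bp for Selp. Mecom, Vwf, Cdkn1a and Cdkn2a had no end summit in any library, although the records of Mecom and Vwf held 5, 23 and 10 and 5, 18 and 6 summits in the young-, old- and ABC-labelled lists. The record of Cdkn1a held 1 summit in each list.

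The comparison of old with young HSCs addressed the effect of age. More genes had an end summit in the library labelled old and none in the library labelled young (3631) than the reverse (347), so 91.3% of the 3978 differing genes were on the old-labelled side (90.4 to 92.1). The highest-scoring old-labelled gene with no young-labelled summit within 5 kb was Retnlg, a secreted protein gene of granulocytes (chromosome 16, 48872608 to 48874498, summit at 48874304, score 48.2). It was followed by Asmt, the last enzyme of melatonin synthesis (35.3), Chm (28.4), Lrif1 (25.5), Spon1 (25.4), the fatty acid transporter gene Slc27a6 (24.6), Hesx1 (24.6) and the circadian receptor gene Nr1d2 (23.4). On the young-labelled side, within that list, such genes were Mrgpra2b (7.79), Clec4a2 (6.93), Rhbg (4.63), Ccno (4.28), Col2a1 (4.16), Lyg2 (4.03), Hspb2 (3.54) and Ifnz (3.37). The 5 kb limit was counted from the record ends only. Inside the records of Spon1 and Lrif1 lay 3 and 1 young-labelled summits, and those of Rhbg and Col2a1 each held 2 old-labelled ones.

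Of the HSC ageing genes, 23 of 30 had an end summit in the old-labelled and 12 in the young-labelled library. The 11 that differed were all on the old-labelled side, and in equal-length lists (16 and 12) 4 were, Cavin2, Mt2, Gpr183 and Egr1. Against 10000 random lists of matched gene length the 11 were at percentile 99.5, below the control genes of other tissues (99.9) and next to megakaryocyte and platelet markers (99.3) and stroma and endothelium (99.1). The other 16 lists lay between 0.120 and 92.4, and in equal-length lists all 20 lay between 5.63 and 97.2, with HSC ageing genes at 89.2. The caveolar gene Cavin2 (7.63) had no young-labelled summit within 5 kb, whereas the immediate early gene Egr1 (7.98) had one at 1178 bp. Of the HSC identity genes 22 of 30 were marked in the old-labelled and 17 in the young-labelled library. That list also held Flt3 and Cd48, which mark progenitors, so its counts are of listed genes and no measure of HSC identity. Equal-length lists gave 17 and 17, with 4 genes on each side. Flt3, the receptor of early multipotent progenitors (chromosome 5, 147330741 to 147400489, score 21.6), and Gfi1b, a transcription factor of the megakaryocyte and erythroid lines (10.5), had old-labelled end summits and no young-labelled summit within 5 kb of an end. The record of Flt3 held 1 young-labelled summit. Cd48 and Hoxb5 were on the young-labelled side, with old-labelled summits only just outside the window, at 1015 and 1003 bp.

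Ferroptosis genes were marked in 29 of 36 cases in the old-labelled and 21 in the young-labelled library. The 8 that differed, all on the old-labelled side, against a median of 6 in random lists (percentile 77.5), included Ptgs2, the inducible prostaglandin synthase (17.0, with no young-labelled summit within 5 kb), and Trp53 (29.1) and Nfe2l2, the regulator of antioxidant genes (51.2), whose nearest young-labelled summits were at 1268 and 1150 bp. In equal-length lists (25 and 21) 5 ferroptosis genes were on the old-labelled side, Ptgs2, Nfe2l2, Por, Trp53 and Alox12, and 1, Hmox1, on the young-labelled side. Sphingolipid genes were marked in 28 and 25 of 40 cases as deposited and in 23 and 25 in equal-length lists. The ceramidase gene Acer2 (8.13) was on the old-labelled side with no young-labelled summit within 5 kb of an end, but 1 inside its record. The ceramide synthase genes Cers6 (10.1) and Cers2 (2.77) were on the young-labelled side, with old-labelled summits at 1122 and 1321 bp. Histone acetylation enzymes were marked in 26 and 22 of 30 cases in the old- and young-labelled libraries (23 and 22 in equal-length lists), with Hdac6 (9.34; no young-labelled summit within 5 kb) and Hdac11 (18.8; 2262 bp) on the old-labelled side and Kat2b (5.59; old-labelled summit at 1090 bp) on the young-labelled side.

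Among inflammatory genes, 20 of 26 NF-kB genes were marked in the old-labelled and 17 in the young-labelled library in both settings, the difference being Nfkb1 (49.1, young-labelled summit at 1184 bp), Il10 (9.50) and Il6 (6.06), the last pair with no young-labelled summit within 5 kb. Interferon response genes were marked in 23 and 22 of 25 cases in both settings, differing by Ifi27l2a (17.2). Senescence and p53 genes were marked in 18 and 15 of 25 cases (16 and 15 in equal-length lists), with the apoptosis gene Bbc3 (10.4) on the old-labelled side and Rb1 (7.95; old-labelled summit at 1035 bp) on the young-labelled side. Glycolysis and hypoxia genes were marked in 18 and 14 of 24 cases (16 and 14), with Hk2 (19.5) and Slc2a1 (14.4) on the old-labelled side and young-labelled summits at 1006 and 1084 bp. In lists of widely used genes most members were marked in both libraries, which left few to differ: oxidative phosphorylation 28 and 28 of 30, autophagy and lysosome 23 and 22 of 24, cell cycle 24 and 22 of 26 (23 and 22 in equal-length lists), and ribosomal proteins 24 and 22 of 26. The equal-length counts of the other 3 were the same as these. With gene ends within 500 bp the direction turned for senescence and p53 genes and for autophagy and lysosome genes, to -1 members gained minus lost in each.

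Markers of other cell types differed in the same direction as deposited. Megakaryocyte and platelet markers were marked in 10 of 16 cases in the old-labelled and 3 in the young-labelled library, with Itga2b, Nfe2 (young-labelled summit at 3609 bp) and Rab27b on the old-labelled side also in equal-length lists (6 and 3). Myeloid markers stood at 16 and 10 of 20, erythroid at 6 and 3 of 15, B cell at 6 and 3 of 16, T and NK cell at 8 and 2 of 20, and stroma and endothelium at 11 and 4 of 18. Of 26 control genes of liver, muscle, pancreas, nerve and other tissues, 11 had an end summit in the old-labelled library, among them Ins2, Apoa1 and Ttr, and none had one in the young-labelled library. In equal-length lists the control genes fell to 1 (Actn2, score 6.39), the stroma and endothelium markers to 3 against 4, and the erythroid markers to 3 against 3, while myeloid markers stood at 14 against 10. B cell markers stood at 4 against 3 and T and NK cell markers at 5 against 2. S100a8 and S100a9, the calprotectin genes of granulocytes and monocytes on chromosome 3, ranked 13 and 17 in the old-labelled and 44 and 41 in the young-labelled equal-length list.

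In equal-length lists 1511 genes were on the old-labelled and 718 on the young-labelled side, and with absence taken as no summit within 5 kb the lists as deposited gave 2268 and 31. Of the 347 genes on the young-labelled side, 91.1% had an old-labelled summit 1 to 5 kb from an end (87.6 to 93.8), and 37.5% of the 3631 on the old-labelled side had a young-labelled one. In equal-length lists the shares were 62.4% and 46.0%. Under the names inside the files no list is a young one.

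**Figure D2:**
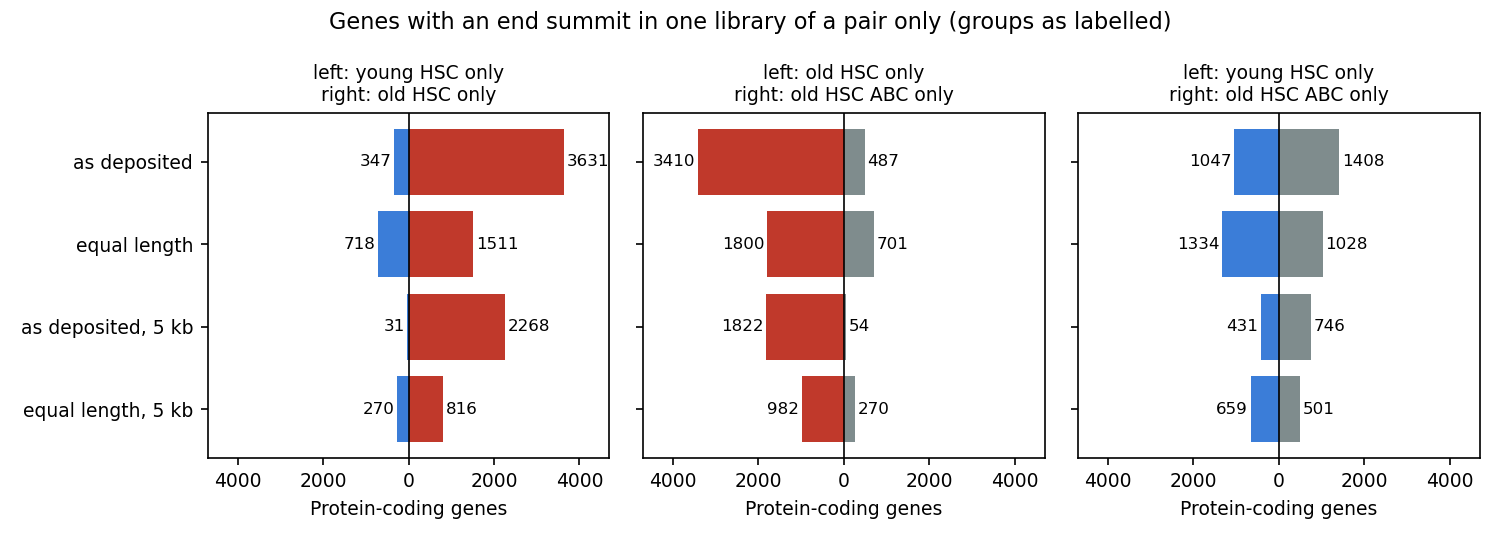
Numbers of protein-coding genes (x axis) with an end summit in one library of a pair only, for the 3 pairs of libraries as labelled and 4 settings (rows). In the pair of young and old ABC the larger side changed with list length, from 1408 genes on the ABC-labelled side as deposited to 1334 on the young-labelled side in equal-length lists.

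The comparison of old HSC ABC with old HSC addressed what the ABC label adds in old cells. Fewer genes had an end summit in the library labelled old ABC alone (487) than in the library labelled old alone (3410), so the ABC-labelled side held 12.5% of the 3897 differing genes (11.5 to 13.6). The strongest old-labelled genes with no ABC-labelled summit within 5 kb were Retnlg (48.2), the mitochondrial serine transporter gene Sfxn1 (36.8), the neighbouring histone genes H2ac18 and H3c14, which shared a summit on chromosome 3 at 96246176 (30.7), the Toll-like receptor adaptor gene Ticam1 (27.5), Creld1 (26.2), the interferon-inducible gene Ifi209 (24.8) and Crcp (24.7). All of these except Retnlg also had an end summit in the young-labelled list. On the ABC-labelled side Xkr6 led with 8.27, followed by Alox12e (4.90), Btnl9, Dhrs2, Fbn1 and Wfdc15b (4.60 each), Pnmal2 (4.59) and Rhbg (4.54). The 5 kb limit was counted from the record ends only. Inside the records of Xkr6, Fbn1, Rhbg and Btnl9 lay 12, 20, 2 and 1 old-labelled summits. Those of Alox12e, Dhrs2, Wfdc15b and Pnmal2 held 0. On the old-labelled side the records of Sfxn1 and Crcp held 1 and 2 ABC-labelled summits.

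By group, 19 of the 20 gene lists had more members on the old-labelled than on the ABC-labelled side. HSC identity genes were marked in 22 cases in the old-labelled and 15 in the ABC-labelled library (17 and 12 in equal-length lists), with the stem cell factor receptor gene Kit (18.4; nearest ABC-labelled summit at 1304 bp), Lyl1 (12.6; 1475 bp) and Gfi1 (8.72; 1607 bp) among the 8 on the old-labelled side. HSC ageing genes stood at 23 and 15, with Egr1 (7.98; nearest ABC-labelled summit 20794 bp away) and Tgm2 (7.75; 6474 bp) on the old-labelled side and none on the other. Ageing genes stood at 16 and 13 in equal-length lists, with Osmr on the ABC-labelled side. Ferroptosis genes stood at 29 and 21 (25 and 20 in equal-length lists), with Nfe2l2 (nearest ABC-labelled summit at 1148 bp), Lpcat3 (13.2; 4523 bp) and Alox12 (11.6; 1825 bp) on the old-labelled side. NF-kB genes stood at 20 and 15, and in equal-length lists at 20 and 13, where the 7 on the old-labelled side were Il10, Nfkb1, Il6, Myd88, Nlrp3, Nfkbia and Tnf (percentile 99.7 of random lists, but 65.9 for the 5 as deposited). Nfkbia and Tnf had ABC-labelled end summits as deposited, which did not reach the equal-length list. The nearest ABC-labelled summits were at 1012 (Nfkb1), 1036 (Il10), 1308 (Myd88), 1569 (Nlrp3) and 53125 bp (Il6). Glycolysis and hypoxia genes stood at 18 and 12, and in equal-length lists (16 and 11) 7 were on the old-labelled side (percentile 99.8, and 93.8 for the 7 as deposited), among them Pkm, the pyruvate kinase gene (14.9; nearest ABC-labelled summit at 7408 bp), Egln3 (15.6; 1023 bp) and Epas1 (11.2; 1074 bp). Pdk1, also among those 7, had an ABC-labelled end summit as deposited. As deposited, the control genes of other tissues (99.955) and megakaryocyte and platelet markers (99.5) stood above the NF-kB and the glycolysis lists. Such percentiles were computed for 6 counts of differing genes in each of 20 lists, both as deposited and in equal-length lists. Further ones were computed for the marked members of each library and among marked genes. All of them describe these libraries only.

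Sphingolipid genes were marked in 28 and 25 cases in the old- and ABC-labelled libraries, with Cers6 (6.90), Cers2 (4.53), Asah1 and the sphingosine 1-phosphate receptor gene S1pr4 (9.21; old-labelled summit at 1136 bp) on the ABC-labelled side and Smpd2 (12.6; ABC-labelled summit at 1026 bp), Sgms1 (10.7; 2374 bp) and Spns2 (9.16; 2599 bp) among the 7 on the other. In equal-length lists both libraries stood at 23, with 5 genes on each side. The ABC-side counts were at percentile 99.1 as deposited and 99.3 in equal-length lists, against a median of 1 gene in random lists. In the equal-length count Smpd3 had an old-labelled end summit as deposited (5.65), just under the 5.86 at which that list started. Cers6 and Cers2 had old-labelled summits at 1122 and 1321 bp. With summits anywhere in a gene record both libraries stood at 36, with 1 gene on each side (Cers1 on the ABC-labelled side). On the ABC-labelled side T and NK cell markers were at percentile 99.38 as deposited and 91.45 in equal-length lists. Histone acetylation enzymes stood at 26 and 24 (23 and 22 in equal-length lists), with Kat8 (12.3; nearest ABC-labelled summit at 1033 bp) and Sirt6 (11.5; 5820 bp) on the old-labelled side. Senescence and p53 genes stood at 18 and 16 (16 and 16), with Bax (11.1; ABC-labelled summit at 1474 bp) and Bbc3 on the old-labelled side and Lmnb1 (8.80; old-labelled summit at 1226 bp) and Rb1 on the ABC-labelled side. Interferon genes stood at 23 and 24 (23 and 23), the difference as deposited being Irf1 (11.1; old-labelled summit at 1202 bp). With scores of at least 5 and 10 the interferon direction turned, to -3 and -11 members gained minus lost, and with summits at 1 gene only to -1. Ribosomal protein genes stood at 24 and 23 (24 and 22), and Rpl13, with an ABC-labelled score of 40.0, had an old-labelled summit at 1043 bp. Oxidative phosphorylation stood at 28 and 27 (28 and 27), autophagy and lysosome at 23 and 22 (23 and 21), and cell cycle at 24 and 22 (23 and 22), with Rrm2 (17.7; ABC-labelled summit at 10239 bp) on the old-labelled side. With gene ends within 500 bp oxidative phosphorylation and cell cycle turned, to 3 and 1 members gained minus lost.

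The myeloid marker Camp, which encodes a granule peptide of neutrophils (chromosome 9, 109847377 to 109849456), had an old-labelled score of 96.7 and a nearest ABC-labelled summit at 4822 bp. Myeloid markers as a whole stood at 16 and 11 in the old- and ABC-labelled libraries (14 and 10 in equal-length lists), and S100a8 and S100a9 ranked 807 and 2253 in the ABC-labelled equal-length list. Megakaryocyte and platelet markers stood at 10 and 4, erythroid at 6 and 4, B cell at 6 and 3, T and NK cell at 8 and 6, stroma and endothelium at 11 and 8, and control genes of other tissues at 11 and 0. In equal-length lists the erythroid (3 and 3) and the T and NK cell markers (5 and 5) no longer differed in number, and the megakaryocyte and platelet (6 and 3), B cell (4 and 3) and control counts (1 and 0) differed by less. Stroma and endothelium turned round in equal-length lists, at 3 and 8, the 5 genes on the ABC-labelled side being Bglap, Vcam1, Kdr, Col1a2 and Cdh5 (percentile 99.985, and 33.6 for the 0 as deposited). All 5 had an old-labelled end summit as deposited. They fell out because the old-labelled equal-length list started at a score of 5.86, the ABC-labelled one at 2.84, so this turn shows no loss from the old-labelled library. In equal-length lists 701 genes were on the ABC-labelled and 1800 on the old-labelled side. A summit of the other library lay 1 to 5 kb from an end for 88.9% of the 487 and 46.6% of the 3410 as deposited, and for 61.5% and 45.4% in equal-length lists. Under the names inside the files the direction of this comparison reversed.

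**Figure D3:**
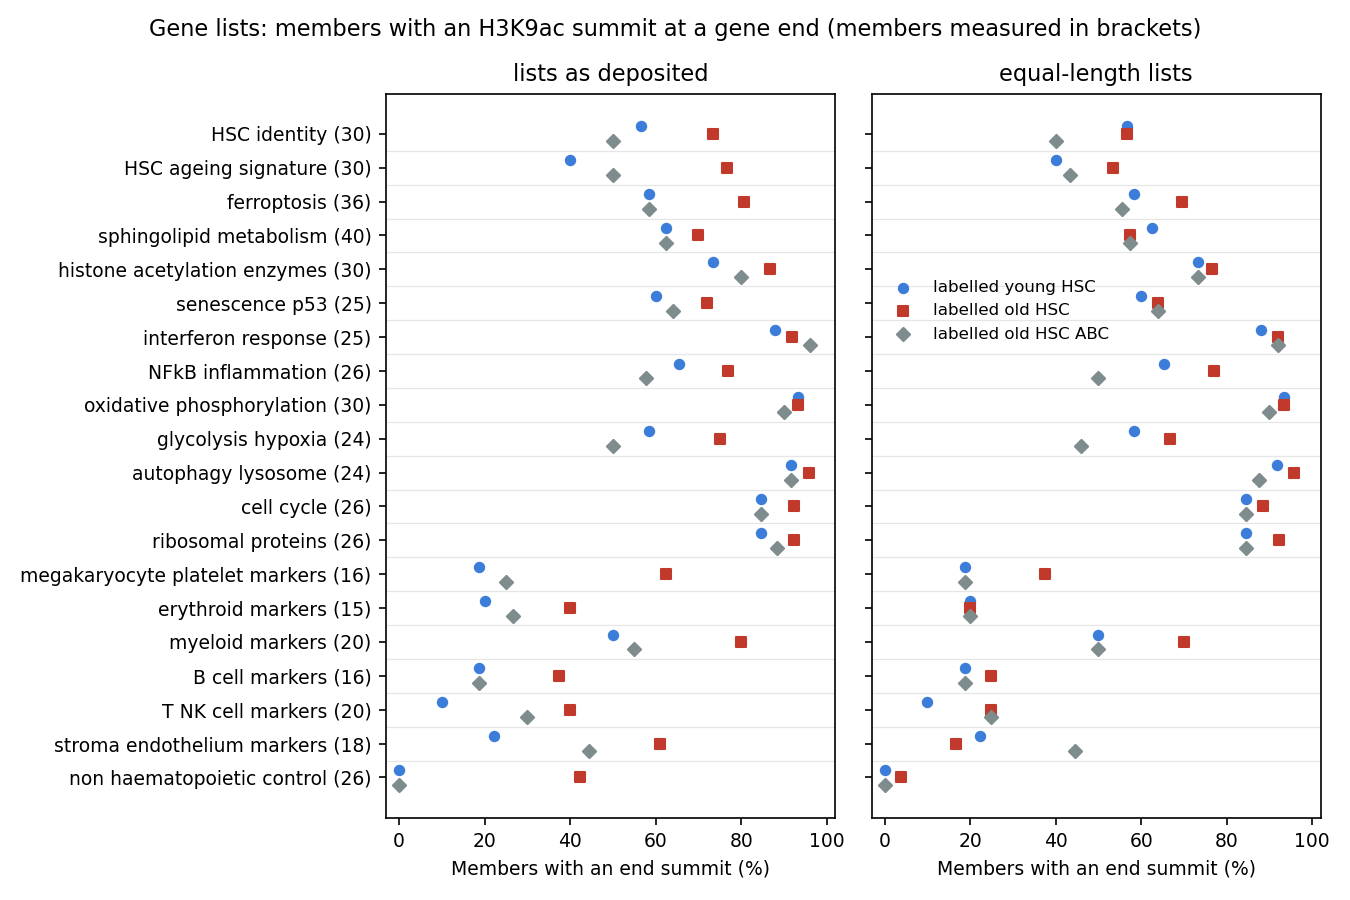
Percent of the measured members of each of 20 gene lists (y axis, members in brackets) that had an end summit (x axis), by library, in the lists as deposited (left) and in equal-length lists (right). The control genes of other tissues stood at 0, 11 and 0 of 26 members in the libraries labelled young, old and old ABC as deposited and at 0, 1 and 0 in equal-length lists.

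The comparison of old HSC ABC with young HSC asked whether the ABC-labelled library had the end summits of the young or of the old one. As deposited, 1408 genes had an end summit in the ABC-labelled library alone and 1047 in the young-labelled library alone, and in equal-length lists the direction turned, to 1028 and 1334. The strongest genes on the ABC-labelled side with no young-labelled summit within 5 kb were Asmt (20.6), Smim13 (12.5), Cnot10 (11.6), the syndecan gene Sdc3 (11.5), Lrif1, Rtl8b (10.6), Gcdh (10.5) and the Fanconi anaemia gene Fancb (10.1), and all 8 had an end summit in the old-labelled list too. Those on the young-labelled side were Tfip11 (13.5), Creld1 (12.7), Sfxn1 (12.7), Polr2g (11.4), Pi4k2a (11.3), Klf10 (10.7), the small RNA effector gene Ago2 (10.6) and Alg13 (10.4), again all with an old-labelled end summit. The records of Cnot10, Sdc3 and Lrif1 each held 1 young-labelled summit. Those of Sfxn1, Pi4k2a and Ago2 held 1, 1 and 2 ABC-labelled summits.

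Ferroptosis and sphingolipid genes had equal numbers of marked members in the ABC- and young-labelled libraries, at 21 and 21 of 36 and at 25 and 25 of 40 as deposited. In equal-length lists they stood at 20 and 21 and at 23 and 25. Ptgs2 (4.60), Trp53 (4.61; young-labelled summit at 1268 bp) and Slc11a2 (4.12; 1621 bp) were on the ABC-labelled side. Hmox1, Lpcat3 (5.18; ABC-labelled summit at 4523 bp) and Aifm2 (4.93; 1597 bp) were on the young-labelled side. HSC identity genes stood at 15 and 17, and in equal-length lists at 12 and 17, the 5 on the young-labelled side being Cd48, Mllt3, Kit, Lyl1 and Hoxb5. Of these Cd48, Hoxb5, Kit and Lyl1 had an ABC-labelled summit just outside the window, at 1021, 1069, 1304 and 1475 bp. For HSC identity genes the direction turned with gene ends within 2 kb and with summits anywhere in a gene record, to 2 members gained minus lost in each. With absence within 5 kb it turned to 1. Glycolysis genes in equal-length lists stood at 11 and 14, with Pdk1, Pkm, Egln3 (ABC-labelled summit at 1023 bp), Epas1 (1074 bp) and Pgk1 on the young-labelled side and Slc2a1 (young-labelled summit at 1084 bp) and Hk2 (1006 bp) on the ABC-labelled side. Stroma and endothelium markers stood at 8 and 4 in both settings, with Bglap, Vcam1, Col1a2 and Cdh5 on the ABC-labelled side. A summit of the other library lay 1 to 5 kb from an end for 47.0% of the 1408 genes on the ABC-labelled and 58.8% of the 1047 on the young-labelled side, and for 51.3% and 50.6% in equal-length lists.

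Of the 3631 genes with an end summit in the old- but not the young-labelled library, 69.8% had none in the ABC-labelled library either (68.3 to 71.3), and of the 347 genes on the young-labelled side 50.4% had one in it (45.0 to 55.8). In equal-length lists these shares were 60.3% and 38.0%. With absence taken as no summit within 5 kb they were 54.9% and 19.4% as deposited and 53.6% and 22.6% in equal-length lists. The lowest score counted also mattered, at 84.6% and 30.9% for scores of at least 10, and summits anywhere in a gene record gave 56.0% and 29.5%. The old-labelled library enters both contrasts: 2535 genes were absent from both other libraries, against 994 for independent lists and a mean of 2237 (2126 to 2303) in 100 simulations that kept the rates of absence within each of 10 bins of old-labelled score. With 1 old-labelled library the shared control could not be split, so part of the excess can come from it. The share without an ABC-labelled end summit was 86.1% in the lowest bin of old-labelled score, 7.89% in bin 7 (38 genes) and 33.3% in bin 9 (30 genes).

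**Figure D4:**
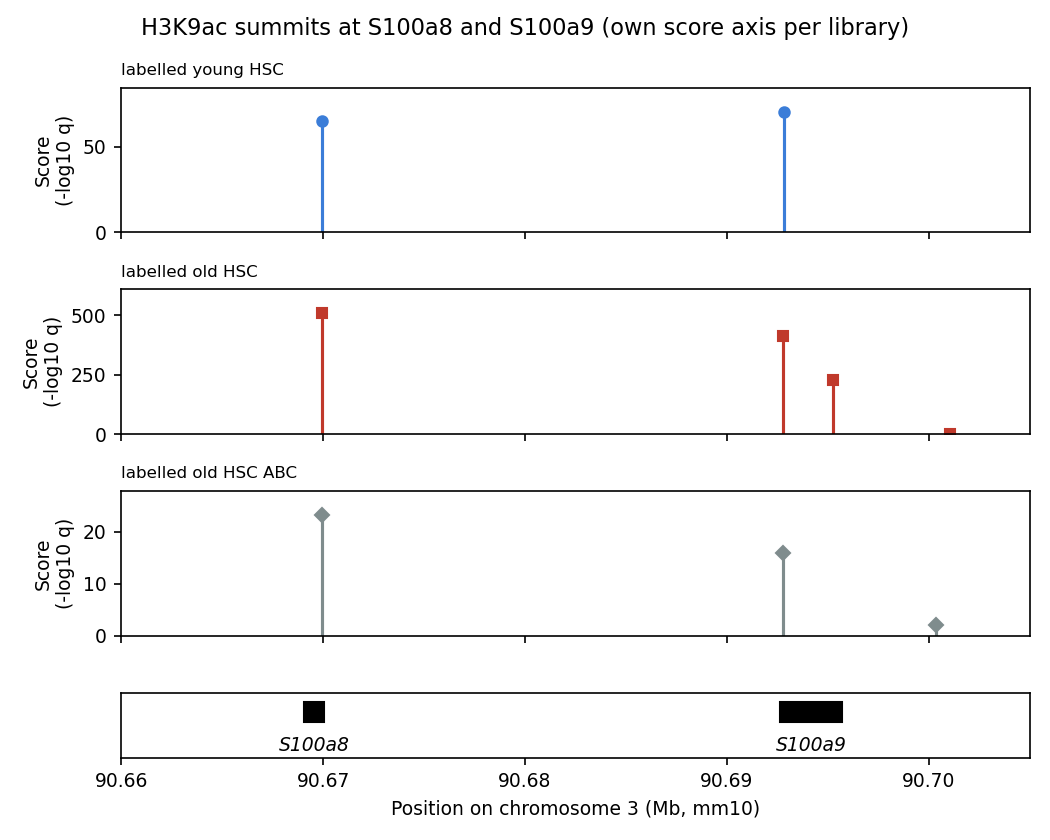
Summits (x axis, position on chromosome 3 in Mb, mm10) around S100a8 and S100a9, with their scores (y axis, -log10 q) on a separate axis for each library, since scores are not comparable between lists. All 3 libraries had a summit near the end of S100a8, at 90669934, 90669927 and 90669924 in the libraries labelled young, old and old ABC.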

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

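All tests of explanations in this part were chosen after the results were seen.

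Summits outside chromosomes 1 to 19, X and Y entered the totals, the shared summits and the equal-length lists, but no comparison of genes. The unplaced contig JH584304 held 20, 31 and 28 summits in the libraries labelled young, old and old ABC, and the mitochondrial chromosome held 8, 8 and 8. They are named here because they lie outside the chromosomes on which genes were compared and no control library was used here to set a level for them. No explanation for them was tested.

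The list labelled old had more summits and more genes with an end summit than the list labelled young. In equal-length lists the ratio of genes with an end summit, old-labelled over young-labelled, was 1.09, against 1.36 as deposited. A limit on list length lowers this ratio by construction. With scores of at least 5 and 10 the ratio was 1.40 and 1.90, and all 3 lists started at nearly the same score, so a looser threshold in the old-labelled list was not seen. Greater depth may still account for the excess, since scores also grow with depth, and wider H3K9ac in old cells stays open, untested; with 1 library per group these cannot be told apart.

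The sample names inside the peak names differed from the labels. If the names were right, the lists labelled young and old ABC would be replicates of old HSC, and might share more with each other than with the third. In equal-length lists 52.8% of young-labelled summits had an ABC-labelled one within 500 bp, against 55.8% with an old-labelled one, and 56.1% of ABC-labelled summits had an old-labelled one. The shares are too close, and too dependent on library quality, to exclude a mislabelled sample, and with 1 library per group the labels and the names cannot be told apart. A true difference between the groups was not tested against it.

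Granulocyte genes were among the strongest summits of the old-labelled list. A list of 7 granulocyte genes, S100a8, S100a9, Camp, Ltf, Ngp, Mmp8 and Ly6g, all of them taken from the myeloid markers, was used to ask whether granulocytes carried into the sorted cells may be the source. Mpo, Elane, Prtn3 and Ctsg of the same markers were not included. Of the 7, 4 had a summit in the top percent of the old-labelled equal-length list (332 summits), 2 in the young-labelled and 0 in the ABC-labelled one. S100a8, S100a9, Ngp and Camp ranked 13, 17, 45 and 137 in the old-labelled list, Ltf and Mmp8 ranked 27849 and 20775, and Ly6g had none in any library. Lyz2, another myeloid marker, which monocytes and macrophages also express and which was not among the 7, ranked 199 in the old-labelled list, 2667 in the young-labelled and 27910 in the ABC-labelled one. The cells were sorted HSCs, a sort that would remove granulocytes, and neither a marked state of these genes in old HSCs nor the share of other cells could be decided, so the explanations cannot be told apart.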

How the results depend on the processing

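Tests with summits anywhere in a gene record, with summits at 1 gene only, with absence within 5 kb, with random lists from marked genes and with groups from the peak names were chosen after the results were seen. Below, young, old and ABC name libraries as labelled. A count is given where it differed from the first value by more than 1.5 times, and a share where it left its 95% counting interval. The cause was not tested unless stated. No paired analysis was possible because each group had 1 library.

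In old against young more genes were on the old side under every alternative run for that comparison. In ABC against old more were on the old side under every alternative with groups from the labels. With groups from the peak names the genes gained minus lost were 3284 and 2923 against the first and second list named old, against -2923 by the labels, a reversal that follows from the exchange of names. In ABC against young the value was 361 as deposited and negative in 4 settings.

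Numbers of summits fell with stricter scores and with equal-length lists. 14349 (young), 42251 (old) and 16287 (ABC) were found with a score of at least 5. 6072 (young), 16689 (old) and 5561 (ABC) were found with a score of at least 10. 33248 (old) was found with equal-length lists.

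The share of summits at gene ends rose with stricter scores and with a wider window. 48.6% (young), 24.4% (old) and 41.0% (ABC) were found with a score of at least 5. 65.2% (young), 46.9% (old) and 61.6% (ABC) were found with a score of at least 10. 28.9% (old) and 27.2% (ABC) were found with equal-length lists. 18.3% (young), 8.28% (old) and 14.4% (ABC) were found with gene ends within 500 bp. 35.9% (young), 18.3% (old) and 29.2% (ABC) were found with gene ends within 2 kb.

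Shares of summits with a neighbour in another list moved too. 84.0% (young in old), 66.9% (young in ABC), 28.5% (old in young), 30.8% (old in ABC), 59.0% (ABC in young) and 80.1% (ABC in old) were found with a score of at least 5. 90.6% (young in old), 66.5% (young in ABC), 33.0% (old in young), 72.6% (ABC in young) and 91.5% (ABC in old) were found with a score of at least 10. 55.8% (young in old), 52.8% (young in ABC), 55.1% (old in young), 55.5% (old in ABC), 52.7% (ABC in young) and 56.1% (ABC in old) were found with equal-length lists. 65.4% (young in old), 49.7% (young in ABC), 20.01% (old in young), 25.6% (old in ABC), 36.5% (ABC in young) and 61.5% (ABC in old) were found with sharing within 250 bp. 85.6% (young in old), 65.2% (young in ABC), 27.2% (old in young), 34.6% (old in ABC), 49.0% (ABC in young) and 80.4% (ABC in old) were found with sharing within 1000 bp.

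Of the numbers of genes with an end summit, these moved. 4523 (young) and 3943 (ABC) were found with a score of at least 10.

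The old against young gene counts moved as follows. 231 (young only) was found with a score of at least 5. 94 (young only) was found with a score of at least 10. 1511 (old only) and 718 (young only) were found with equal-length lists. 883 (young only) was found with gene ends within 500 bp. 151 (young only) was found with gene ends within 2 kb. 88 (young only) was found with summits anywhere in a gene record. 2268 (old only) and 31 (young only) were found with absence within 5 kb. 816 (old only) was found with absence within 5 kb in equal-length lists.

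For ABC against old the gene counts that moved were these. 239 (ABC only) was found with a score of at least 5. 66 (ABC only) was found with a score of at least 10. 1800 (old only) was found with equal-length lists. 1034 (ABC only) was found with gene ends within 500 bp. 260 (ABC only) was found with gene ends within 2 kb. 151 (ABC only) was found with summits anywhere in a gene record. 54 (ABC only) and 1822 (old only) were found with absence within 5 kb. 270 (ABC only) and 982 (old only) were found with absence within 5 kb in equal-length lists.

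For ABC against young they were these. 903 (ABC only) was found with a score of at least 5. 682 (ABC only) was found with a score of at least 10. 746 (ABC only) and 431 (young only) were found with absence within 5 kb. 501 (ABC only) and 659 (young only) were found with absence within 5 kb in equal-length lists.

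Genes gained minus lost moved or changed sign. -316 (ABC against young) was found with a score of at least 5. -4668 (ABC against old) and -580 (ABC against young) were found with a score of at least 10. 793 (old against young), -1099 (ABC against old) and -306 (ABC against young) were found with equal-length lists. 575 (ABC against young) was found with gene ends within 2 kb. 866 (ABC against young) was found with summits anywhere in a gene record. -1768 (ABC against old) was found with absence within 5 kb. 546 (old against young), -712 (ABC against old) and -158 (ABC against young) were found with absence within 5 kb in equal-length lists.

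Gene lists with more members gained than lost changed in number. 0 (ABC against old) and 5 (ABC against young) were found with a score of at least 5. 0 (ABC against old) and 2 (ABC against young) were found with a score of at least 10. 5 (ABC against young) was found with equal-length lists. 3 (ABC against old) was found with gene ends within 500 bp. 0 (ABC against old) was found with gene ends within 2 kb. 0 (ABC against old) was found with summits anywhere in a gene record. 0 (ABC against old) was found with summits at 1 gene only. 0 (ABC against old) was found with absence within 5 kb. 11 (old against young), 3 (ABC against old) and 5 (ABC against young) were found with absence within 5 kb in equal-length lists.

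So did gene lists with more members lost than gained. 11 (ABC against young) was found with a score of at least 5. 10 (ABC against young) was found with a score of at least 10. 2 (old against young) and 7 (ABC against young) were found with equal-length lists. 3 (old against young) and 7 (ABC against young) were found with gene ends within 500 bp. 2 (ABC against young) was found with gene ends within 2 kb. 2 (ABC against young) was found with absence within 5 kb. 1 (old against young), 12 (ABC against old) and 8 (ABC against young) were found with absence within 5 kb in equal-length lists.

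Of the genes on the old side of old against young, the share also without an ABC end summit moved. It was 76.3% with a score of at least 5, 84.6% with a score of at least 10, 60.3% with equal-length lists and 67.3% with gene ends within 2 kb. It was further 56.0% with summits anywhere in a gene record, 71.6% with summits at 1 gene only, 54.9% with absence within 5 kb and 53.6% with absence within 5 kb in equal-length lists.

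Of those on the young side, the share with an ABC end summit moved. It was 45.0% with a score of at least 5, 30.9% with a score of at least 10, 38.0% with equal-length lists and 32.5% with gene ends within 2 kb. It was further 29.5% with summits anywhere in a gene record, 42.8% with summits at 1 gene only, 19.4% with absence within 5 kb and 22.6% with absence within 5 kb in equal-length lists.

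List members gained minus lost changed sign in these cases. -4 (histone acetylation, ABC against young), -3 (interferon, ABC against old), -2 (ribosomal proteins, ABC against young), -3 (myeloid, ABC against young) and -1 (T and NK cell, ABC against young) were found with a score of at least 5. -3 (histone acetylation, ABC against young), -11 (interferon, ABC against old), -5 (interferon, ABC against young), 2 (glycolysis, ABC against young), -2 (ribosomal proteins, ABC against young) and -4 (myeloid, ABC against young) were found with a score of at least 10. -2 (sphingolipid, old against young), -1 (stroma and endothelium, old against young) and 5 (stroma and endothelium, ABC against old) were found with equal-length lists. -1 (senescence and p53, old against young), -4 (senescence and p53, ABC against young), 3 (oxidative phosphorylation, ABC against old), 1 (oxidative phosphorylation, ABC against young), -1 (autophagy, old against young), 1 (cell cycle, ABC against old) and -3 (ribosomal proteins, ABC against young) were found with gene ends within 500 bp. 2 (HSC identity, ABC against young) was found with gene ends within 2 kb. 2 (HSC identity, ABC against young) was found with summits anywhere in a gene record. -1 (senescence and p53, ABC against young), -1 (interferon, ABC against old) and 2 (oxidative phosphorylation, ABC against young) were found with summits at 1 gene only. 1 (HSC identity, ABC against young) was found with absence within 5 kb. -1 (sphingolipid, old against young), 2 (sphingolipid, ABC against old), -2 (histone acetylation, ABC against young), -1 (erythroid, ABC against young), -1 (myeloid, ABC against young), 1 (T and NK cell, ABC against old) and 3 (stroma and endothelium, ABC against old) were found with absence within 5 kb in equal-length lists.

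The differences in list members (20 lists in 3 comparisons) that stayed, moved and changed sign numbered 24, 31 and 5 with a score of at least 5, 13, 41 and 6 with a score of at least 10, 19, 38 and 3 with equal-length lists and 26, 27 and 7 with gene ends within 500 bp. They numbered 33, 26 and 1 with gene ends within 2 kb, 19, 40 and 1 with summits anywhere in a gene record, 46, 11 and 3 with summits at 1 gene only, 24, 35 and 1 with absence within 5 kb and 10, 43 and 7 with absence within 5 kb in equal-length lists. The differences at named genes that stayed numbered 152 with a score of at least 5, 84 with a score of at least 10, 205 with equal-length lists and 130 with gene ends within 500 bp. They numbered 118 with gene ends within 2 kb, 84 with summits anywhere in a gene record, 182 with summits at 1 gene only, 95 with absence within 5 kb and 103 with absence within 5 kb in equal-length lists. None of these changed sign. For list genes the rule that chose them required the difference in equal-length lists, so that setting is no check on them. The other named genes were chosen as the highest-scoring with no summit within 5 kb in the other library. Neither absence within 5 kb nor equal-length lists are a check on those. Among list genes no summit lay within 5 kb for 18 of 40 and 0 of 10 (old and young side of old against young), 1 of 13 and 10 of 38 (ABC and old side of ABC against old), and 11 of 31 and 7 of 25 (ABC and young side of ABC against young). With random lists drawn from genes marked in either library, the percentiles in equal-length lists fell for some lists and rose for others. They were 96.8 for NF-kB genes and 98.9 for glycolysis genes on the old side of ABC against old, lower than with all genes. Nfkbia, Tnf and Pdk1, counted there, had an ABC end summit as deposited. On the old side of old against young the percentiles fell to 82.9 for HSC ageing genes and rose to 97.5 for megakaryocyte and platelet, 98.2 for T and NK cell and 92.4 for control genes. Members marked in either library numbered only 16, 6, 5 and 1 in these lists, so the value for control genes rests on Actn2 alone. For stroma and endothelium on the ABC side of ABC against old the value rose from 99.985 to 100, although as deposited all of these genes also had an old end summit.

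Merging summits closer than 500 bp and keeping only chromosomes 1 to 19 and X moved no value beyond these limits. The use of only the 5' end of a gene record was not run, since the gene table gives no strand. Read depth is not given in the sources used here, so what it limits could not be computed, and equal-length lists even out the number of summits and not the depth.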

Other observations

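All tests in this part were chosen after the results were seen.

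Summits with no summit of either other library within 5 kb numbered 1507 in the young-labelled list (4.53%), 45204 in the old-labelled (41.6%) and 3348 in the ABC-labelled one (7.38%). In the ABC-labelled list the highest-ranked lay on chromosome 6 at 4762466, at 1949 bp from Peg10, at rank 124 of that list, and the next was at rank 3096. In the old-labelled list they lay on chromosome 17 at 3029955 (rank 229), on chromosome 2 at 5379328 in Camk1d (488) and on chromosome 1 at 193227818 in Hsd11b1 (638). In the young-labelled list the first rank was 5112, held by a summit on chromosome 7 at 47488069 in Mrgpra2b and by one on chromosome X. These were chosen after their values were seen.

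A hypothesis was that the ABC-labelled list takes the young state at genes that differ between the old- and young-labelled lists. The old-labelled list would then stand apart from the other pair most often. As deposited it did, in 52.5% of the 5165 genes not alike in all 3 lists, but that list was also the longest. In equal-length lists the old-labelled list stood apart in 33.4% of 3546 such genes (31.8 to 35.0) and the ABC-labelled list in 37.1% (35.5 to 38.8), of which 889 of 1317 genes lacked a summit in that list alone. The young-labelled list stood apart in 29.5%. The intervals cover counting error only, and with 1 library per group a gap of this size decides nothing for or against the hypothesis, which stays open.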
